A study of Mus musculus with 6 samples.

How the data were processed

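ATAC-seq libraries were made from 6 samples of splenic CD4+ T cells on day 7 of EAE, 3 from WT and 3 from Sub1-KO mice. Nuclei were released with mild detergents, treated with a transposase and amplified by PCR, per the labels' protocols. The labels give the molecule as RNA, while the protocol they describe is for DNA. Reads were trimmed with Trimmomatic, aligned with bowtie2, used to call peaks with MACS2 and annotated with ChIPseeker, per the labels' protocols. The build was mm10, per the submitters' processing notes. The protocols also name MEME and DiffBind, and no output of these was used here. Versions, filters, the shifting of reads for the transposase, the removal of duplicate or mitochondrial reads and the way in which replicates were merged are not given in the sources used here.

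The deposited values, per the file headers, are positions and widths in bp, an annotation class, the distance to the nearest start site, and the assigned gene. There is 1 annotated list per genotype. The lists hold no peak score, fold enrichment, q value or read number and no column per replicate, so depth is unknown and regions could be ranked by width only. Width stands in for strength imperfectly, since a wide region need not be a strong one. In every case the end minus the start plus 1 equalled the width, so positions count from 1. Region names hold running numbers in genome order, of which 22.3% in WT and 24.1% in KO are skipped; the reason is not given in the sources used here.

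A region was called shared where it overlapped a region of the other list by at least 1 bp. Chance overlap was described with 100 circular shifts of the KO list within chromosomes. Annotation classes and the promoter, within 3 kb of a start site, were those of the deposited annotation. A gene was called promoter-accessible in 1 genotype only where the other list had no promoter region assigned to it. This call follows the assigned gene, so a gene whose promoter region was assigned to a neighbour counts as having none. Regions per gene were counted from the assigned gene. For places with skipped numbers, each region in 1 list only was set between the nearest listed regions of the other list, and the numbers missing between these were counted. The expected share came from all such gaps of similar length.

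Gene lists, 24 in all, were fixed before the data were examined, matched by symbol or synonym to the genes in the lists, and described by members, regions, promoter regions and the median and mean KO minus WT difference in regions per gene. A list's percentile is its place among 10000 random lists of the same size matched on regions per gene, or, for promoter regions in 1 list only, on the width of the widest promoter region. Percentiles describe these lists and are not p-values, since genes are not replicates. Lists share members: Il17a, Il17f and Csf2 are in both the Th17 and the cytokine list, and Tyrobp is in both the myeloid and the CD8 T and NK list. The values of 1 of the 24 lists and of 1 gene are not reported here. A further list of 71 myeloid genes was written later, before it was counted.

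Genes were named by a rule fixed at the same time: Sub1 and Dock2, the 10 genes with the largest excess of regions in each list (predicted genes left out), up to 4 members per gene list with a promoter region in 1 genotype only, widest first, and the 5 widest regions in 1 list only per genotype. Of a list with more such members, Il3, Ccl4, Lyz2, Itgam and Mpo were added so that each count is named in full, and other genes added later are stated as such where they appear. Genes of the further myeloid list were named after their values were seen.

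Alternatives were other overlap rules (50% of the shorter region, reciprocal 50%, a gap of up to 500 bp), regions at least as wide as the median of 632 bp, equal list lengths, chromosomes 1 to 19 and X, promoters within 1 kb and regions within 10 kb of the start site. Added after seeing the data were promoter calls by overlap with any region, the treatment of skipped numbers, the mean difference beside the median, 1 gene per locus of 200 kb, and matching on promoter width. No genome sequence was used here, so base composition and motifs were not examined.

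The steps were tested on simulated data before use. Shared and unshared calls were right for 99.99% of 34348 WT regions against a simulated KO list. That list was made by dropping WT regions and moving the others by less than their width. Kept regions were bound to overlap, so this value checks the code only and not calls on narrowed or split regions. The counts of overlapping regions differed from bedtools by 0. Of 200 random lists drawn with no effect, 7.5% lay under the 5th percentile (95% interval 4.26 to 12.1, which includes 5%). Of 200 lists of 25 genes in which 12 members were shifted by 2 regions, 65% lay under the 5th percentile. These lists were drawn only from genes with several regions, so the rate does not apply to lists of fewer genes or of genes with few regions. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.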

Results

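Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in CD4+ T cells from the spleens of wild-type (WT) and Sub1-knockout (KO) mice. The cells were taken on day 7 of experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis. Sub1 encodes a nuclear DNA-binding protein that acts as a transcriptional coactivator, and Dock2 encodes a guanine nucleotide exchange factor that activates Rac and that lymphocytes need for migration. The title of the series links the T cell receptor, SUB1 and DOCK2 to the migration of CD4+ T cells in autoimmunity, and the comparison of the genotypes asks where accessible regions differ when Sub1 is deleted. Each genotype had 3 libraries, and the data analysed here are 1 merged list of accessible regions per genotype, with positions, widths and gene annotation (mm10). A merged list carries no spread between replicates, so no difference between the lists has a replicate check and no test was made. The read depth of the libraries is unknown, and the 95% intervals given (exact Clopper-Pearson) cover counting error only.

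Sub1 itself (ENSMUSG00000022205) had 3 assigned regions in each list, and each of the 3 overlapped a region of the other list. Its promoter region lay at chromosome 15, 11994944 to 11996333 (1390 bp) in WT and 11994934 to 11996333 (1400 bp) in KO, within 1 kb of the start site. This was the only region in either list that touched the gene body (11981339 to 11996983). The deleted part of Sub1 is not given in the sources used here, so an open promoter in the KO list does not check the deletion.

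Dock2 (ENSMUSG00000020143, chromosome 11, 34226815 to 34783892) had 9 assigned regions in WT and 7 in KO. Its promoter region was listed in both genotypes, at 34782515 to 34784157 (1643 bp) in WT and 34782509 to 34784088 (1580 bp) in KO. No KO region overlapped 4 of the WT regions: those in introns at 34738918 to 34739177 and 34773245 to 34773596, that upstream of the gene at 34796084 to 34796546, and that at 34228951 to 34229358, which is annotated to a promoter of a short transcript near the 3′ end. The first 3 of these lay between consecutively numbered KO regions. The KO list held 1 intronic region that no WT region overlapped, at 34236366 to 34236607. The first-intron WT region at 34770495 to 34771952 (1458 bp) spanned 2 KO regions, at 34770579 to 34770991 and 34771162 to 34771844. The deficit in KO was not stable: the KO minus WT difference was −2 with all regions, 0 for regions at least as wide as the median and for those within 10 kb of a start site, and 1 when the WT list was shortened to the length of the KO list.

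**Figure D1:**
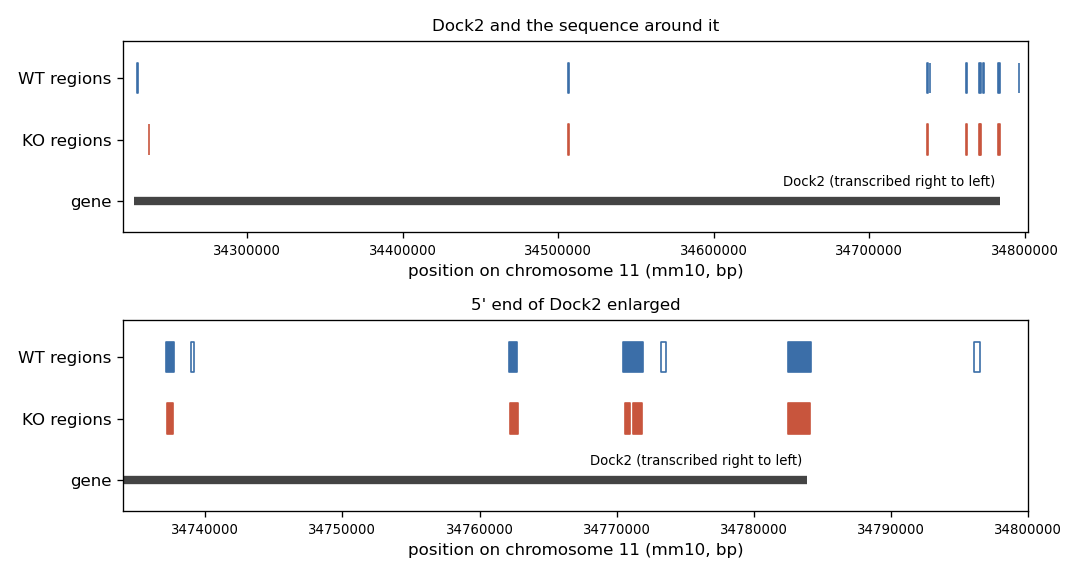
Accessible regions assigned to Dock2 along chromosome 11 (mm10, position in bp), WT in blue and KO in red, with the gene span in grey; the lower panel enlarges the 5′ end. Filled boxes overlap a region of the other list and open boxes do not: 4 of 9 WT regions and 1 of 7 KO regions are open, while the promoter region is in both lists.

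Across the genome the WT list held 34348 regions covering 24.1 Mb and the KO list 26922 regions covering 18.99 Mb, a WT to KO ratio of 1.28 in number and 1.27 in covered length. A KO region overlapped 25701 WT regions by at least 1 bp, or 74.8% (95% interval 74.4 to 75.3), whereas a WT region overlapped 25899 KO regions, or 96.2% (96.0 to 96.4). This left 8647 regions in WT only and 1023 in KO only. After shifting the KO list along the chromosomes 100 times, 1.53% of WT regions overlapped on average, with 1.83% the highest value. Regions in 1 list only were narrow, with a median width of 398 bp in WT against 748 bp for shared WT regions, and 384 bp in KO against 659 bp for shared KO regions. Where exactly 1 WT region matched 1 KO region (25138 pairs), the WT region was the wider in 71.6% of pairs, and the median KO to WT width ratio was 0.930.

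Accessible promoters were shared more often than introns and intergenic sites. Promoter regions, within 3 kb of a start site, made up 53.1% of the WT list (95% interval 52.6 to 53.6) and 58.9% of the KO list (58.4 to 59.5). Introns held 21.6% of WT and 18.2% of KO regions, and distal intergenic sequence 19.9% and 18.3%. KO regions overlapped 84.5% of WT promoter regions, 60.9% of intronic and 67.1% of distal intergenic WT regions. Among the 8647 regions in WT only, 32.7% were at promoters and 33.6% in introns. Part of this contrast went with width, since WT promoter regions had a median of 792 bp and the other WT regions 500.0 bp. When WT regions were split into 5 width classes, the overlapped share went from 33.8% of the narrowest to 99.6% of the widest promoter regions, and from 27.3% to 96.9% of regions elsewhere.

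**Figure D2:**
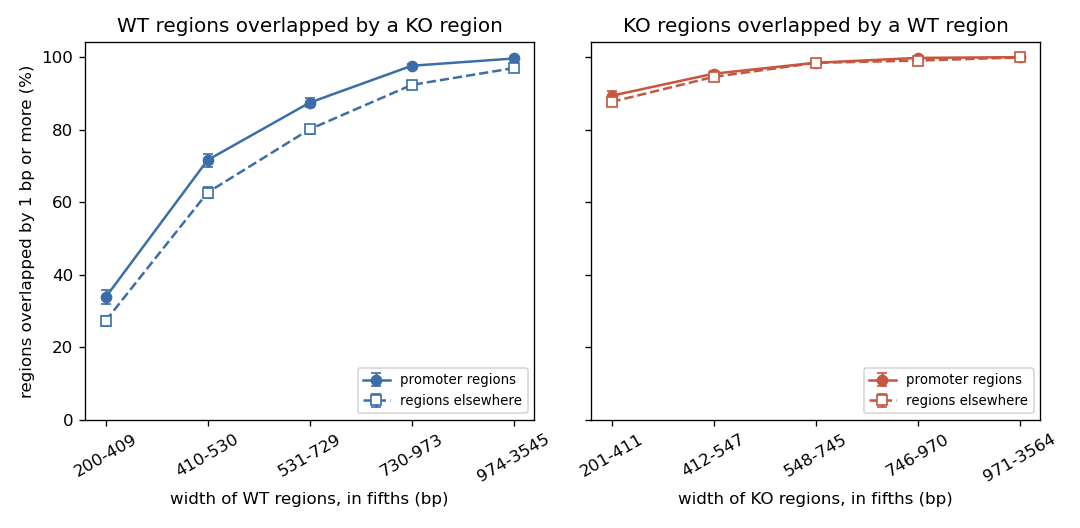
Percentage of regions overlapped by a region of the other genotype (vertical axis) in 5 classes of region width in bp (horizontal axis), for WT regions (left) and KO regions (right); filled circles are promoter regions, open squares are regions elsewhere, and bars are 95% exact intervals for counting error. Among WT regions of 200 to 409 bp, 33.8% at promoters and 27.3% elsewhere had a KO counterpart, against 99.6% and 96.9% of those of 974 bp or more.

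The region names in each list count upwards along the genome and skip numbers, so that 9883 of the 44231 numbers of the WT list and 8538 of the 35460 numbers of the KO list name no region analysed here. Of the regions in WT only, 70.1% lay where the KO numbering skips at least 1 region, against 34.8% expected from the lengths of the gaps between listed regions, and for those in KO only the values were 86.6% against 36.6%. A region in 1 list only is thus often at a place where the other list may hold an unlisted region. Counting such places as shared left 2587 regions in WT only and 138 in KO only.

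Of 14327 genes with a promoter region in either list, 12743 had one in both, 1327 (9.26%) in WT only and 257 (1.79%) in KO only. Counted over all regions, 6308 of 18927 genes had more regions in WT, 875 had more in KO and 11744 had equal numbers. The genes with the largest differences are named next, a ranking that favours genes with many regions. Nfatc2, a transcription factor activated by calcium signalling downstream of the T cell receptor, had 11 regions in WT and 4 in KO, and Bcl11b, a transcription factor of T cell commitment, had 15 and 8. Fyb, an adaptor of T cell receptor signalling to integrins, had 16 and 9, Prkch, a protein kinase C of T cells, had 26 and 19, and Ripor2 had 12 and 5. Sgms1 had 20 and 12, Map4k4 16 and 8, and Pced1b, Sh3kbp1 and Ankrd11 each 15 and 8. All 10 of these genes had a promoter region in both lists. The largest KO excesses were smaller: Samsn1, which encodes an adaptor of haematopoietic cells, had 6 regions in WT and 10 in KO, Thrb 3 and 6, Lhfpl2 1 and 4, and the interleukin-1 receptor kinase gene Irak2 4 and 6. Cd9 and Chn2 also had 4 and 6, Slc37a3 5 and 7, Zfp827 and Rpl11 3 and 5, and Mvb12b 2 and 4. The KO regions that no WT region overlapped numbered 4 for Samsn1, 3 each for Thrb and Lhfpl2, 2 each for Cd9, Chn2 and Mvb12b, and only 1 each for Irak2, Slc37a3, Zfp827 and Rpl11. In these last 4 genes the other extra region arose where 2 KO regions overlapped a single WT region, and the regions of Slc37a3 covered 3431 bp in WT and 3277 bp in KO.

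These counts depended on the length of the lists. With the WT list shortened to its 26922 widest regions, 643 genes had a promoter region in WT only and 647 in KO only, and 2666 genes had more regions in WT against 2725 in KO. With regions at least as wide as the median, 3269 genes had more regions in WT, and the differences of Ankrd11, Samsn1, Slc37a3, Chn2, Rpl11 and Mvb12b changed sign. Fyb changed sign at equal list lengths. A reciprocal overlap of 50% gave 472 genes in KO only, and counting places with skipped numbers as shared gave 333 genes in WT only and 20 in KO only.

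T cell receptor signalling genes had 174 regions in WT and 118 in KO, with fewer in KO for 27 of 33 genes, equal numbers for 5 and more for 1, Cd6. All 5 KO regions of Cd6 overlapped a WT region. Besides Nfatc2, and chosen after their values were seen, the Src kinase gene Fyn had 16 regions in WT and 10 in KO, the protein kinase C gene Prkcq 10 and 6, the phospholipase gene Plcg1 7 and 3, and Cd3e of the receptor complex 4 and 1. All 33 genes had a promoter region in both lists. For regions at least as wide as the median, 5 genes had one in WT only and 0 in KO only. The mean KO minus WT difference was −1.70 regions per gene, at percentile 0.590 of 10000 random lists matched on regions per gene, whose mean was −1.13. The percentile lay between 0.430 and 1.20 in the 4 other settings tried. The median difference, −1, lay at percentile 49.7. A median of whole numbers is coarse, so this value does not show which genes lowered the mean.

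Regulatory T cell genes had 67 regions in WT and 44 in KO, fewer in KO for 11 of 16 genes, with a mean difference of −1.44 at percentile 1.46. Examples chosen after their values were seen were Il2ra, the interleukin-2 receptor alpha chain, with 11 and 6 regions, and Nrp1 with 8 and 4. The percentile of the mean was 15.02 at equal list lengths. The median difference, −1, which was the planned measure, lay at percentile 10.9. Naive and memory T cell genes had 137 and 101 regions, fewer in KO for 14 of 18, with a mean difference of −2 at percentile 17.4 and a median of −2 at percentile 4.29. In that group Lef1, a transcription factor of naive T cells, had its promoter region (1522 bp) listed under the gene in WT only, although a KO region assigned to a neighbouring transcript overlapped it.

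**Figure D3:**
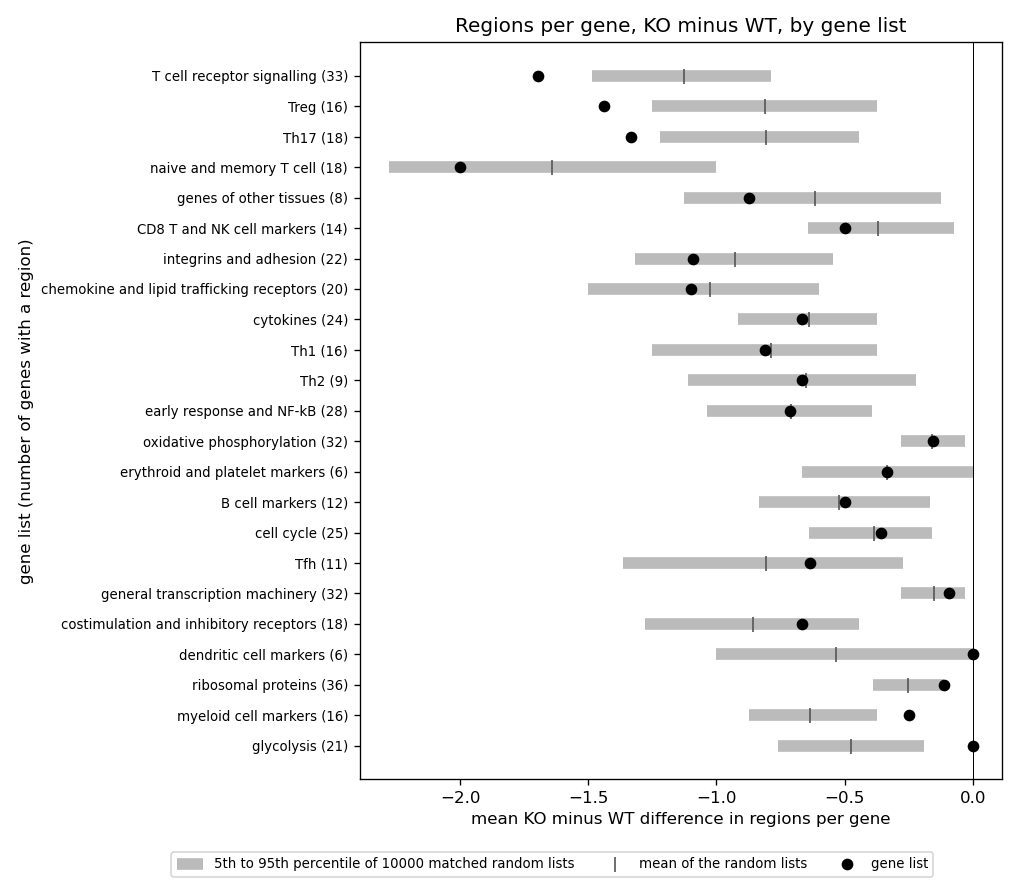
Mean KO minus WT difference in regions per gene (horizontal axis) for 23 of the 24 gene lists (vertical axis, with the number of genes that have a region), as black points, against the 5th to 95th percentile (grey bars) and mean (ticks) of 10000 random lists matched on regions per gene. T cell receptor signalling (−1.70), Treg (−1.44) and Th17 (−1.33) lie below the grey bars, and glycolysis (0) and myeloid cell markers (−0.250) above. At each end 1.2 lists are expected if the percentiles are exact. The mean was added after the data were seen. By the planned median difference these lists lay at percentiles 49.7, 10.9, 30.9, 50.6 and 99.3, in the same order.

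Genes of the Th17 programme had 67 regions in WT and 43 in KO, fewer in KO for 12 of 18, equal for 5 and more for 1, Irf4. All 5 KO regions of Irf4 overlapped a WT region, while 2 of its 4 WT regions had no KO counterpart. The mean difference of the list was −1.33 at percentile 1.67, which became 13.4 with regions within 10 kb of the start site. The median difference, −1, which was the planned measure, lay at percentile 30.9. A promoter region was listed in WT only for 4 of 15 genes, namely the cytokine genes Il17a, Il17f and Csf2 and the interleukin-1 receptor gene Il1r1, where random lists matched on promoter width held 1.04 on average. With 1 gene per locus of 200 kb, 3 of 14 loci remained, at percentile 99.2, and 2 of 14, at 94.6, when overlap by any KO region was also excluded. Il17a (ENSMUSG00000025929) had 5 regions in WT and 2 in KO, and its WT promoter region lay at chromosome 1, 20730642 to 20731282 (641 bp), at a place where the KO numbering skips no region. Il17f (ENSMUSG00000041872) had 2 and 1, with a WT promoter region at 20784166 to 20784608 (443 bp), and both genes kept shared intergenic regions. Il1r1 (ENSMUSG00000026072) had 6 and 3, and a KO region annotated to an intron overlapped its widest promoter region (905 bp). Rora, a transcription factor gene of the list chosen after its values were seen, had 16 and 10.

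Cytokine genes had 56 regions in WT and 40 in KO, fewer in KO for 13 of 24 genes, with a mean difference of −0.667 at percentile 43.0, within the range of random lists. Their promoter regions stood apart from this, as 7 of 19 members had one in WT only and 0 in KO only, where width-matched random lists held 2.90 in WT only on average. They were Il17a, Il17f, Csf2 (chromosome 11, 54249245 to 54249802), Il3 (54264611 to 54264918), Ccl4 (83662280 to 83662493), Ltb (chromosome 17, 35194143 to 35194799) and Lta (35204522 to 35205504). The count lay at percentile 99.9 of the random lists, and 1.84% of random sets of 24 lists held a list as extreme. A KO region overlapped the Lta promoter region, and the 7 genes lie close together in several cases, so that they are not independent. With no overlap by any KO region allowed, 6 genes remained, at percentile 99.1, and with 1 gene per locus of 200 kb, 3 of 13 loci (Lta, Il17a and Csf2), at 99.2. With both conditions 2 of 13 loci (Il17a and Csf2) remained, at 95.9. Counting places with skipped numbers as shared left 1 cytokine gene and 1 Th17 gene, which are the same gene, Il17a.

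**Figure D4:**
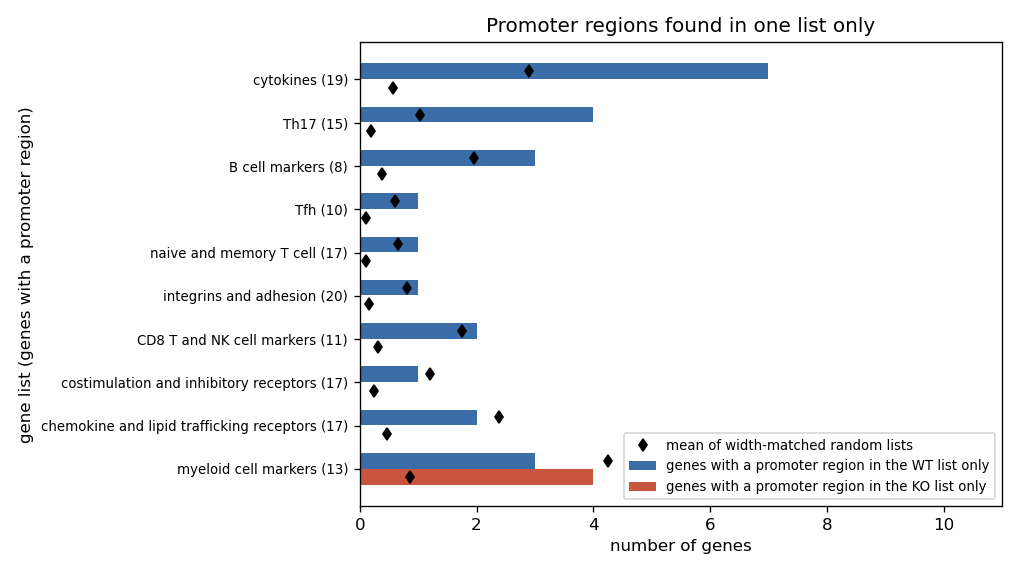
Number of genes with a promoter region in the WT list only (blue) or the KO list only (red) in the gene lists that had any (vertical axis, with the number of genes that have a promoter region), and the mean of random lists matched on promoter width (diamonds). Cytokines (7 in WT only against 2.90) and Th17 (4 against 1.04) exceed the random mean in WT, and myeloid cell markers (4 in KO only against 0.868) in KO. Smaller excesses in WT are those of B cell markers (3 against 1.96), CD8 T and NK markers (2 against 1.75), integrins (1 against 0.804), naive and memory genes (1 against 0.66) and Tfh (1 against 0.606).

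Genes of cell migration had fewer regions in KO, within the range of matched random lists. Chemokine and lipid trafficking receptors had 87 regions in WT and 65 in KO, fewer in KO for 14 of 20 and more for 0, with a mean difference of −1.10 at percentile 38.5. Their promoter regions in WT only were those of Ltb4r1, a leukotriene B4 receptor, and Ccr9, the latter overlapped by a KO region assigned to another gene. Integrins and adhesion genes had 92 and 68 regions, fewer in KO for 12 of 22, at percentile 25.5, and the promoter region of Jaml was listed in WT only. Chosen after their values were seen, the Rac exchange factor gene Tiam1 had 16 regions in WT and 10 in KO, and Elmo1, whose product binds DOCK2, had 10 and 5.

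With all regions, other T cell groups lay within the range of random lists. Th1 genes had 61 regions in WT and 48 in KO (percentile 45.2), Th2 genes 24 and 18 (47.1), follicular helper genes 40 and 33 (68.8) and costimulatory and inhibitory receptors 69 and 57 (77.4). Early response and NF-kB genes had 97 and 77 regions (48.7), and all 28 had a promoter region in both lists. The promoter regions of Ascl2, a follicular helper transcription factor, and Cd40lg, the CD40 ligand, were listed in WT only. For regions at least as wide as the median, the Th2 list lay at percentile 0.0750 and the follicular helper list at 2.61.

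Housekeeping genes had few regions each and lay within the range of random lists, except glycolysis genes. Ribosomal protein genes had 50 regions in WT and 46 in KO (percentile 94.3), general transcription genes 40 and 37 (74.6), oxidative phosphorylation genes 42 and 37 (49.0) and cell cycle genes 53 and 44 (55.0), and in these 4 groups every member with a region had a promoter region in both lists. Glycolysis genes had 46 regions in each list, with 1 more in KO for Eno1, Ldhb and Tpi1, 1 fewer for Hif1a, Pfkp and Pkm, and equal numbers for the other 15 genes. These 6 were named after their values were seen. Both of the 2 KO regions of Tpi1 overlapped a WT region. The mean difference of the glycolysis list, 0, lay at percentile 99.8, and at 80.9 for regions at least as wide as the median. The median difference, also 0, which was the planned measure, lay at percentile 50.6.

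Markers of other cell types were measured to describe what the isolates held besides CD4+ T cells. Myeloid cell markers had 25 regions in WT and 21 in KO, fewer in KO for 7 of 16 and more for 6, with a mean difference of −0.250 at percentile 97.1, which lay between 89.2 and 99.6 in the other settings. The promoter regions of 4 of 13 myeloid genes were listed in KO only, where width-matched random lists held 0.868. These were the lysozyme gene Lyz2 (chromosome 10, 117282184 to 117282423), the macrophage growth factor receptor gene Csf1r (chromosome 18, 61108383 to 61109007), the neutrophil gene S100a8 (chromosome 3, 90668875 to 90669231) and the lectin gene Clec4d (chromosome 6, 123259894 to 123260562). In WT only were those of Cd68, Itgam and Mpo. With promoters within 1 kb, 2 genes remained in KO only, against 0.845 in random lists, and 3 in WT only, and for regions at least as wide as the median 1 and 0. All 4 KO regions lay where the WT numbering skips at least 1 region, as did 86.6% of all regions in KO only. Counting these places as shared left none of the 4. The mean of the list changed sign, to 0.286, at equal list lengths.

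B cell markers had 22 regions in WT and 16 in KO (percentile 54.1), with the promoter regions of Cd22, Ebf1 and Fcmr in WT only. CD8 T and NK cell markers had 25 and 18 (22.8), with the promoter regions of the NK receptor genes Klre1 and Klra1 in WT only. Dendritic cell markers had 15 in each list (93.7), erythroid and platelet markers 10 and 8 (49.8) and genes of other tissues 19 and 12 (20.2). In single other settings, CD8 T and NK markers lay at percentile 1.09 (within 10 kb), erythroid and platelet markers at 3.56 (wide regions) and dendritic cell markers at 97.6 (equal list lengths). By the mean difference, 3 of the 24 lists lay under the 5th and 2 above the 95th percentile, where 1.2 are expected at each end if the percentiles are exact. By the planned median, T cell receptor signalling, Treg, Th17 and glycolysis lay between these percentiles. Myeloid markers (99.3) and naive and memory genes (4.29) did not. In 9 lists more promoter regions were in WT only than in KO only, against 15 with regions at least as wide as the median and 2 with skipped places counted as shared.

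The widest regions in 1 list only were mostly at promoters. In WT they were assigned to Ism1 (chromosome 2, 139677169 to 139678810, promoter), Ptpra (chromosome 2, 130539088 to 130540497, promoter), Zbtb38 (chromosome 9, 96740104 to 96741438, intron), the predicted gene Gm48293 (chromosome 9, 40743571 to 40744903, intron of another gene) and Rbpms2 (chromosome 9, 65629617 to 65630940, promoter). In KO they were assigned to the netrin gene Ntn4 (chromosome 10, 93640901 to 93642300, promoter), Epb41l4a (chromosome 18, 34006225 to 34007482, promoter), Cxadr (chromosome 16, 78301303 to 78302311, promoter), Igf2r (chromosome 17, 12754527 to 12755521, intron of another gene) and 1700048O20Rik (chromosome 9, 121937312 to 121938279, promoter). Their widths ran from 968 bp at 1700048O20Rik to 1642 bp at Ism1. All 10 lay where the numbering of the other list skips at least 1 region.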

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

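No paired analysis was possible because the merged lists carry no values per replicate. For the same reason, leaving out each replicate and keeping regions found in at least 2 replicates were not run, and no score allowed a stricter threshold, so width was used as planned. The WT to KO ratio of 1.28 became 1.23 for regions at least as wide as the median and 1 by construction at equal list lengths. The share of WT regions overlapped, 74.8%, became 72.1% with reciprocal overlap, 76.1% with a gap allowed, 77.0% for wide regions, 86.8% at equal lengths and 92.5% with skipped places counted as shared. The share of KO regions overlapped, 96.2%, became 92.0%, 96.5%, 94.8%, 87.7% and 99.5% in the same order. Promoter regions made up 70.1% of WT and 76.7% of KO regions among wide regions, 58.0% of WT regions at equal lengths, and 43.4% and 50.6% with promoters within 1 kb. Genes with a promoter region in WT only, 1327, became 643 at equal lengths and 333 with skipped places as shared. Those in KO only, 257, became 472 with reciprocal overlap, 647 at equal lengths and 20 with skipped places as shared. Genes with more regions in WT, 6308, became 3269 for wide regions and 2666 at equal lengths, where genes with more in KO, 875, became 2725. Gene lists with more promoter regions in WT only than in KO only, 9, became 15 for wide regions and 2 with skipped places as shared. Equal lengths remove narrow regions from WT alone, which shifts every count toward KO. There the list means turned to 0.0476 for integrins, 0.0556 for costimulation and for ribosomal proteins, 0.2 for Tfh, 0.107 for early response, 0.0313 for general transcription, 0.0625 for oxidative phosphorylation, 0.0909 for B cell, 0.286 for myeloid and 0.167 for erythroid and platelet genes, and the differences of Dock2 and Fyb to 1 each. For wide regions the myeloid mean turned to 0.143, Ankrd11 to 1, Samsn1, Slc37a3, Chn2 and Mvb12b to −1 and Rpl11 to −2. The cause of these changes was not tested. By the mean difference, the T cell receptor list stayed at or under percentile 1.20 throughout, while Th2 (0.0750), Tfh (2.61) and erythroid and platelet genes (3.56) for wide regions, and CD8 T and NK genes (1.09) within 10 kb, were low in that setting alone. Over all alternatives, 33 of the main values stayed and 27 moved, and 140 values of named genes stayed, 24 moved and 8 changed sign. The settings on skipped places, on overlap with any region and on 1 gene per locus were chosen after seeing the data.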

Other observations

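In windows of 200 kb, the largest numbers of WT regions without a KO counterpart were 12 of 21 around Rhoh (chromosome 5, 65800001 to 66000000), 10 of 20 around Lef1 (chromosome 3, 131000001 to 131200000) and 10 of 14 around Pik3r5, a regulatory subunit of phosphoinositide 3-kinase gamma (chromosome 11, 68400001 to 68600000). They were followed by windows with 9 each: 9 of 24 around Cd69 (chromosome 6, 129200001 to 129400000), 9 of 22 around Cd5 (chromosome 19, 10600001 to 10800000), 9 of 21 around Adam15 and Efna1 (chromosome 3, 89200001 to 89400000), 9 of 19 around Ikzf3 (chromosome 11, 98400001 to 98600000) and 9 of 19 around Fnbp1 and Usp20 (chromosome 2, 31000001 to 31200000). In KO the largest numbers were 4 of 11 around Samsn1 (chromosome 16, 75800001 to 76000000) and 4 of 11 around Tifa and Alpk1 (chromosome 3, 127600001 to 127800000). Windows with 3 lay around Psap, Mrpl14, Rassf2, Rbm47, C3ar1 and Fpr1. These windows were picked by their values and have no chance value beside them. Gene families named by the start of their symbols gave no sign of a common shift: of 86 families, 3 lay under the 5th and 4 above the 95th percentile of 2000 matched random lists.

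Tests chosen after the result was seen were, in what follows, those on the highest region numbers, on covered length and on the Th17 list, and the checks on sets of lists, on 1 gene per locus, on the widths of KO regions and on the myeloid regions in KO only by setting. The first pattern weighed is the larger number of regions in WT. Regions left out of the lists do not account for it alone, since the highest region numbers still stand at a ratio of 1.25, nor does the joining of neighbours, since covered length stands at 1.27. More B cells or more myeloid cells in the WT isolate would lower their markers in KO more than other genes: this is argued against as the whole cause by myeloid markers at percentile 97.1 (at least 89.2 in every setting) and by B cell markers at 54.1 (at least 42.0 in 3 other settings), while a smaller share of B cells stays open, since the value was 11.5 within 10 kb of the start site. A lower depth or enrichment of the KO libraries cannot be told apart from other causes: the overlapped share of WT regions went up with width by at least 65.8 percentage points, but that of KO regions also went up, by 10.6 at promoters and 12.2 elsewhere, so narrow regions are less often matched in either direction. An effect of Sub1 deletion on accessibility stays open and untested, because there is 1 merged list per genotype.

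The second pattern is that the promoter regions of Lyz2, Csf1r, S100a8 and Clec4d were in KO only, of which 2 remained with promoters within 1 kb (against 0.845 in random lists, percentile 88.0) and 1 among wide regions (84.0). A candidate source is more myeloid cells in the KO isolate of CD4+ T cells: in the further list of 71 myeloid genes, 48 had a region and 13 of their regions were in KO only, against 3.01 in random lists (percentile 100), though among wide regions it was 3 against 1.19 (93.7). Myeloid cell markers held 9 regions in WT only and 6 in KO only. The further list held 22 regions in WT only, with fewer regions in KO for 15 genes and more for 10. That list had a mean difference of −0.167, at percentile 99.45 but at 57.8 among wide regions, and 1 gene with a promoter region in WT only (Fgr) and 4 in KO only, which became 4 and 1 among wide regions and 4 and 3 with promoters within 1 kb, and S100a9, Csf3r, Lcn2 and C1qa had no assigned region among those analysed here. Unlisted WT regions at the same places may also account for it, since 4 of 4 KO regions, and 12 of the 13 of the further list, lie where WT numbers skip. Of all regions in KO only, 86.6% lie at such places, so these counts are not particular to myeloid genes. Weakness near the calling threshold cannot be told apart. The median width of the 4 promoter regions, 491 bp, is under the lower quartile of 534 bp of KO promoter regions. However, promoter regions in KO only are narrow in general (median 391 bp). These explanations are not exclusive, and an effect of Sub1 deletion stays open. Of random sets of 24 lists, drawn gene by gene and counted for promoter regions in KO only, 4.78% held a list as extreme.

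The third pattern is the cytokine promoter regions in WT only. Weak promoters lost below the threshold in KO cannot be told apart from a cytokine-specific difference: the count lay at percentile 99.9 of width-matched lists, above the 99th set in advance to exclude this, and stayed above it with 1 gene per locus (99.2) or with no overlap by a KO region allowed (99.1), but a lost locus needs both conditions, and with both it was 95.9. Unlisted KO regions at the same places cannot be told apart either, since 5 of 7 genes have a promoter region where KO numbers skip, Il17a and Lta being the exceptions. Of all regions in WT only, 70.1% lie at such places, so this count is not particular to cytokine genes. Fewer Th17 cells in the KO isolate are a candidate explanation, with the mean difference of the Th17 list at percentile 1.67. However, the value was 13.4 within 10 kb, the planned median difference lay at percentile 30.9, and Il17a, Il17f and Csf2 are in both lists. As a hypothesis, the Il17a promoter and the promoter regions of Il1r1, which no skipped number touches, may be the places to measure with replicates.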
